A study of Danio rerio with 32 samples.

How the data were processed

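The deposited gene counts of both experiments were used as the starting point. According to the submitters' processing notes, reads of experiment 1 were checked with FastQC 0.11.7, trimmed with Trim Galore 0.6.5, aligned with STAR 2.7.3a and counted per gene with HTSeq 0.11.1. Those of experiment 2 were processed with FastQC 0.12.1, fastp 0.24.0, STAR 2.7.11, SAMtools 1.22.1, MultiQC 1.32 and featureCounts of Subread 2.1.1. The notes give the genome build GRCz11 (danRer11) and state neither the annotation release nor the strand setting. Experiment 1 used strand-specific poly(A) libraries with dUTP marking, and experiment 2 used stranded single-end libraries with molecular identifiers made by a sequencing company. Whether reads with the same identifier were collapsed before counting is not stated. The deposited unit in experiment 1 was raw reads per gene, with no normalization by the authors, and rows that name no gene were left out of library sizes. The deposited table of experiment 2 held expected counts, made by the authors with featureCounts before deposit and partly fractional for a reason not stated; 84.2 to 90.51% of the values above 0 in a library were whole within 0.005, and all were rounded. A table of variance-stabilised values that the submitters made for experiment 2 was not used. Spike-in features, 92 in number, were left out of the tests.

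Each experiment was fitted separately in R 4.3.3 with edgeR 4.0.16, with 1 coefficient per group and all groups of the experiment in 1 fit. Library sizes were scaled by TMM factors, genes were kept by filterByExpr on the groups, and differences were tested by the quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 without a fold minimum. Of 32520 genes in the files, 22742 were tested in experiment 1 and 16671 in experiment 2, with 16427 tested in both. The biological coefficient of variation was 12.5% in experiment 1 and 16% in experiment 2. Log2 fold changes are those of the fit with a prior count of 0.125; SE is the fold change over the square root of F. CPM is the count divided by the TMM-scaled library size, on the usual scale of edgeR. The labels do not say how many larvae, tanks or clutches a library holds, so each p measures spread between samples of unknown independence. No pairing of libraries by replicate number was found: in 0 of 15 pairs of groups in experiment 1 and 0 of 6 in experiment 2 did every matched pair of libraries correlate above 0.1. A weaker pairing is not excluded. The comparisons, tests, thresholds, gene lists and the rule for naming genes were set before the data were examined.

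The 40 gene lists comprised 17 lists of cell type markers and 23 lists of processes. Members were matched by symbol without regard to case; where a listed symbol was missing, a trailing number after a point and a trailing a or b were removed, and families of ribosomal proteins and collagens were matched by name pattern without ribosomal protein kinases and binding proteins. Symbols are printed as the gene table writes them, some in capital letters; 6136 genes share their symbol with another gene, and such genes are printed with their identifier. Each list was tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, 2-sided and adjusted over the 40 lists, again with the correlation estimated from the data, and with fry, which tests whether the genes of a list move one way on balance. The preset assumes a small correlation between genes, and of all calls made with it the 4 that held with the estimated one are named where they occur. Members passing are counted after adjustment over all genes tested and adjusted over the list alone. In the named-gene rule, each comparison could name pllp, up to 6 higher and 6 lower genes with the largest fold change among those called, with a mean of at least 2 CPM, no overlap between the libraries of the groups (which chance gives in 10% of genes for 3 against 3) and a symbol other than a clone name, and up to 4 called members of each list with the smallest p. For interactions the rule on overlap was not used. Some genes named by the rule are not reported here. For a gene with 0 counts in a group the lowest fold change was taken against 3 counts over the whole group, which covers counting error only.

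Overlaps between comparisons are set beside the number expected from the numbers called. For comparisons that share EK libraries, 20 simulations drew controls anew from the fitted means and dispersions and set unchanged groups against them. Principal components used log2 CPM with a prior count of 2. Alternatives planned were RLE and upper quartile scaling, no filter, a strict filter of 50 counts in every library of a group, a replicate block, a fit of only the groups compared, DESeq2 1.42.0 and leaving out each library in turn. Alternatives added after the data were seen were thinning of experiment 1 to the median depth of experiment 2, leaving out the most abundant feature, fits without replicate 3 of pd1245 on LP or without replicate 2 of EK on HP of experiment 2, and the groups compared without replicate 3 of pd1245 on LP. The main test and camera at the preset correlation were tried, for some of the comparisons, on simulated data in which 200 genes were changed. Those data had independent genes, the same dispersion of a gene in every group and no outlying library. They do not test the filter, the naming rule or a spread that differs between groups. Median fold changes of all genes moved by at most 0.04 log2 units between scalings.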

Results

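RNA was sequenced from whole zebrafish larvae at 20 days after fertilization, in 32 libraries of 2 experiments. Experiment 1 held the wild-type strain EK and larvae with the pllp mutations pd1116 or pd1245, each on a high protein (HP) or a low protein (LP) diet, with 3 libraries in each of the 6 groups. Experiment 2 held EK and a pd1245 line that the submitters call adapted, on the same 2 diets, with 3 libraries per group on HP and 4 per group on LP. pllp encodes plasmolipin, a small membrane protein of the MAL family that acts in apical and endosomal trafficking of gut epithelium. The submitters describe pd1245 in experiment 1 as a new mutation with a survival defect under nutritional restriction, and pd1116 as an old mutation whose defect has adapted. Counts assigned to genes were 24059178 to 29147958 per library in EK on HP, 23046748 to 25125961 in EK on LP, 23424727 to 28469884 in pd1116 on HP and 19838912 to 27157211 in pd1116 on LP. They were 21664463 to 28291407 in pd1245 on HP and 21300799 to 25195397 in pd1245 on LP. In experiment 2 the libraries held 3713048 to 11064054 counts in EK on HP, 10991080 to 12200600 in adapted pd1245 on HP, 10521998 to 12929536 in EK on LP and 9788601 to 12593479 in adapted pd1245 on LP. Expression is given as mean CPM (counts scaled to library size) ± SD over the libraries of a group.

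The first component separated libraries by line and diet only in part. In experiment 1 it held 32.6% of the variance, and replicate 3 of pd1245 on LP scored 94.3 on it against 39.2 and 46.9 for the other pd1245 libraries on LP. That library gave 14.46% of its counts to ribosomal protein genes, which encode the protein part of the ribosome, against at most 9.072% in every other library of experiment 1. Its share for malat1, a long nuclear noncoding RNA, was 1.173% against at most 0.5827%, and its scaling factor was 0.8317 against 0.9707 to 1.056. In experiment 2 replicate 2 of EK on HP held 3713048 counts and scored −74.3 on the first component, which held 25.6% of the variance.

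**Figure D1:**
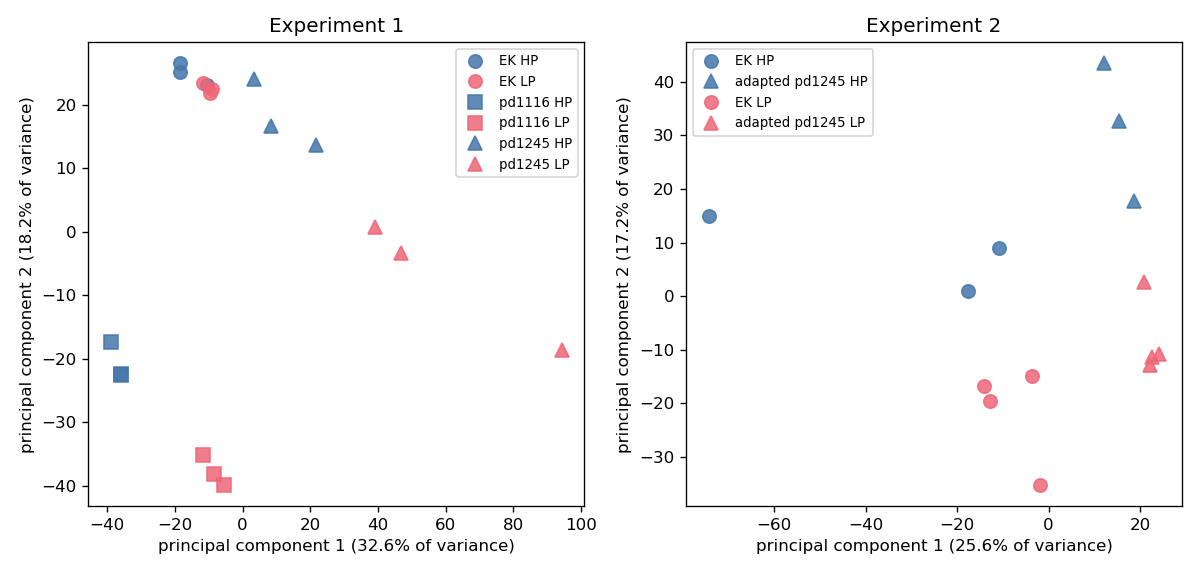
Scores of each library on principal components 1 and 2 of log2 CPM, by experiment; each point is a library, coloured by diet and shaped by line. Replicate 3 of pd1245 on LP sits at 94.3 on component 1 of experiment 1, and replicate 2 of EK on HP at −74.3 in experiment 2.

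The mutated gene itself, pllp (ENSDARG00000062756), lay lower in every mutant group than in EK of the same experiment and diet, although not all of these differences passed the test. In experiment 1 EK held 11.9 ± 0.597 CPM on HP and 15.1 ± 2.17 CPM on LP (SD, n = 3). pllp fell in pd1116 on both diets, to 6.81 ± 0.308 CPM on HP (log2 fold change −0.81, adjusted p = 0.0102) and 7.13 ± 0.800 CPM on LP (−1.08, adjusted p = 7.13e-04). On HP this call was lost without replicate 2 of EK (adjusted p = 0.0509) or replicate 1 of pd1116 (adjusted p = 0.0583). In pd1245 it fell on LP, to 5.50 ± 1.89 CPM (−1.43, adjusted p = 3.21e-05), while on HP it stood at 9.54 ± 0.535 CPM (−0.32, adjusted p = 0.343). Diet lowered pllp within pd1245 (−0.77, adjusted p = 0.00747), and the diet response differed from that of EK (−1.11, SE 0.24, adjusted p = 0.0145). Both of these calls were lost when only the compared groups were fitted (adjusted p = 0.151 and 0.0548) and when counts were thinned to the depth of experiment 2 (adjusted p = 0.0731 and 0.0882). In the adapted line pllp held 6.60 ± 1.08 CPM on HP (n = 3) and 6.90 ± 0.845 CPM on LP (n = 4), against 32.8 ± 3.93 and 30.7 ± 6.33 CPM in EK. These falls were the largest measured for pllp (−2.30 on HP, adjusted p = 1.42e-06; −2.16 on LP, adjusted p = 1.56e-07). They were taken against a higher EK level than in experiment 1, measured with another library kit. The CPM of the adapted line itself lay within the range of the mutant groups of experiment 1.

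**Figure D2:**
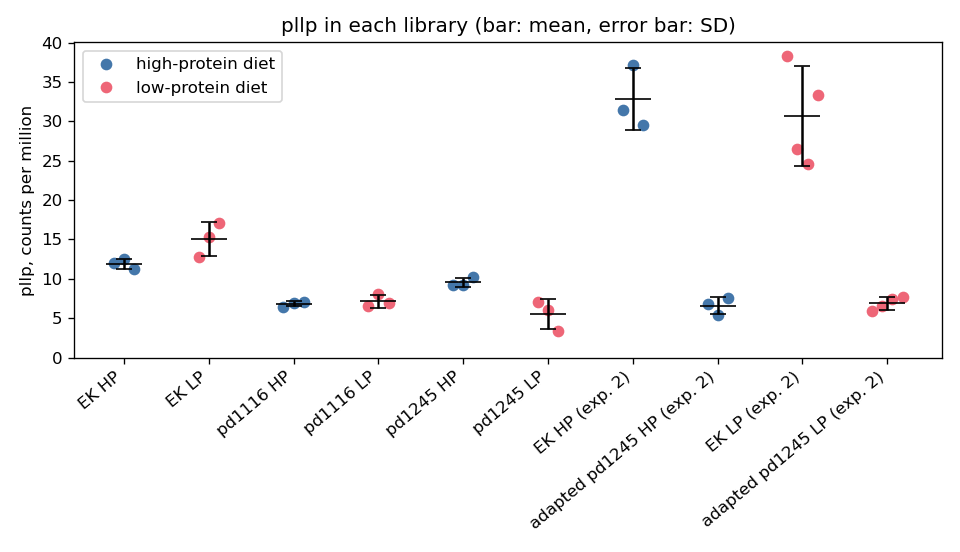
Expression of pllp in CPM on the y axis for each group of both experiments; points are libraries, bars are means and error bars are SD. EK held 11.9 and 15.1 CPM in experiment 1 and 32.8 and 30.7 CPM in experiment 2, and every mutant group had a lower mean in its own experiment.

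How the new mutation differs from wild type under restriction was asked by comparing pd1245 with EK on LP. Genes of the intestinal cells that take up protein, of liver secretion, of cartilage and bone, and of red blood cells were lower in pd1245. ctsbb, a lysosomal cathepsin of the protein-absorbing enterocytes, fell from 204 ± 28.3 CPM in EK to 48.5 ± 8.40 CPM (SD, n = 3). LGMN, a lysosomal asparaginyl endopeptidase, fell from 518 ± 53.5 to 173 ± 10.2 CPM, and amn, which encodes amnionless, the partner of cubilin in endocytic protein uptake, from 16.9 ± 0.627 to 5.47 ± 1.08 CPM. tfa, a transferrin that carries iron in blood, fell from 2670 ± 132 to 557 ± 206 CPM, and ahsg2, a fetuin, from 124 ± 12.6 to 12.1 ± 2.69 CPM. ptprq, a receptor-type tyrosine phosphatase, rose from 4.12 ± 0.367 to 37.2 ± 5.09 CPM, and SLC15A2, a peptide transporter, fell from 18.7 ± 4.57 to 3.07 ± 0.820 CPM.

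Of the 23 measured genes of protein uptake in lysosome-rich enterocytes, 18 fell and 0 rose (18 fell when adjusted over the list alone; camera adjusted p = 1.69e-10, adjusted p = 0.29 with an estimated correlation). Of 29 genes of anterior enterocytes and lipid absorption, 22 fell, among them the apolipoproteins apoa4a (−1.85) and apoa4b.3 (−1.49), and the list gave 22 adjusted over the list alone (camera adjusted p = 5.91e-11, adjusted p = 0.29 with an estimated correlation). All 15 erythrocyte genes fell, including alas2, which starts heme synthesis in red cells (−1.26), cahz, a carbonic anhydrase (−1.20), and the globin hbae3 (−1.05), with 15 adjusted over the list alone (camera adjusted p = 1.2e-11, adjusted p = 0.29 with an estimated correlation). Among hepatocyte secreted proteins 18 of 27 fell and 1 rose, TTR (transthyretin, a thyroid hormone carrier, 1.72), and 19 fell adjusted over the list alone (camera adjusted p = 1.12e-09, adjusted p = 0.316 with an estimated correlation). Of 29 cholesterol synthesis genes 19 fell and 2 rose. The falls included the sterol enzymes HSD17B7 (−2.10) and SC5D (−2.06), and 22 fell adjusted over the list alone (camera adjusted p = 2.66e-09, adjusted p = 0.316 with an estimated correlation). Cell cycle genes fell in 48 of 78 cases and collagen and matrix genes in 38 of 59, with 55 and 47 adjusted over the list alone (camera adjusted p = 4.08e-16 for each, adjusted p = 0.316 with an estimated correlation). Of 27 bone and cartilage genes 19 fell and 1 rose (21 and 1 adjusted over the list alone; camera adjusted p = 8.71e-11, adjusted p = 0.346 with an estimated correlation). CENPF, a kinetochore protein, went from 33.2 ± 1.93 to 11.0 ± 5.14 CPM, and COL1A1, a chain of type I collagen, from 1330 ± 140 to 496 ± 146 CPM. Ribosome biogenesis genes rose in 48 of 73 cases and ribosomal protein genes in 54 of 84, with 53 and 73 adjusted over the list alone (camera adjusted p = 2.18e-14 and 2.1e-10, adjusted p = 0.316 and 0.615 with an estimated correlation). Without replicate 3 of pd1245 on LP, 17 ribosomal protein genes rose, 41 biogenesis genes rose, and 45 cell cycle, 34 matrix, 17 bone and cartilage, 13 erythrocyte, 17 protein uptake, 19 anterior enterocyte, 19 hepatocyte and 21 cholesterol synthesis genes fell. edgeR called 7232 genes changed, 3639 higher and 3593 lower, of which 1190 changed at least 2-fold. Fitting only the groups compared gave 3268, and doing so without replicate 3 of pd1245 on LP gave 7359.

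Which genes respond to restriction in the new mutation was asked by comparing LP with HP within pd1245. Genes for the uptake and breakdown of dietary protein in lysosome-rich enterocytes were lower on LP, as were genes of sterol synthesis, endoplasmic reticulum folding and the extracellular matrix. LGMN fell from 374 ± 99.8 to 173 ± 10.2 CPM and ahsg2 from 64.6 ± 23.9 to 12.1 ± 2.69 CPM (SD, n = 3). SC5D fell from 25.1 ± 11.9 to 8.36 ± 1.64 CPM, and PDIA4, a disulfide isomerase of the endoplasmic reticulum, from 63.5 ± 5.58 to 26.8 ± 9.06 CPM. TRIB3, a pseudokinase induced by the integrated stress response, rose from 40.4 ± 4.74 to 87.7 ± 33.5 CPM, ULK2, an autophagy kinase, from 152 ± 20.8 to 259 ± 45.9 CPM and LPIN1, a phosphatidate phosphatase, from 129 ± 43.0 to 362 ± 126 CPM. Of the 23 protein uptake genes 14 fell (16 adjusted over the list alone), including ctsbb (−1.32) and amn (−1.30), and the list was called lower (camera adjusted p = 1.02e-09, adjusted p = 0.388 with an estimated correlation). Of 29 cholesterol synthesis genes 15 fell and 0 rose (17 and 1 adjusted over the list alone; camera adjusted p = 3.19e-07, adjusted p = 0.388 with an estimated correlation). Collagen and matrix genes fell in 23 of 59 cases, 37 adjusted over the list alone, as for SPARC, a collagen-binding glycoprotein (−0.86), and LUM, the proteoglycan lumican (−1.30) (camera adjusted p = 5.23e-15, adjusted p = 0.388 with an estimated correlation). Of 55 glutathione and antioxidant genes 21 fell and 2 rose, with gstt1b, a glutathione transferase, at −1.09 (26 and 2 adjusted over the list alone; camera adjusted p = 1.75e-09, adjusted p = 0.388 with an estimated correlation). Ribosomal protein genes rose in 54 of 84 cases and cell cycle genes fell in 23 of 78, with 77 and 34 adjusted over the list alone (camera adjusted p = 2.03e-15 and 3.06e-11, adjusted p = 0.444 and 0.388 with an estimated correlation). Of 50 endoplasmic reticulum folding genes 21 fell and 1 rose (21 and 2 adjusted over the list alone; camera adjusted p = 5e-06, adjusted p = 0.388 with an estimated correlation). Without replicate 3 of pd1245 on LP 8 ribosomal protein genes rose and 8 cell cycle genes fell, while 14 protein uptake, 14 cholesterol synthesis, 20 matrix, 26 glutathione and 13 endoplasmic reticulum folding genes fell. In all 4346 genes changed, 2122 higher and 2224 lower, of which 467 changed at least 2-fold. Fitting only these 2 groups called 0 genes (4731 at an unadjusted p under 0.05 in edgeR, while DESeq2 over all groups called 4937), and 954 when replicate 3 on LP was also left out. Leaving out 1 library gave 2853 without replicate 1 on HP, 1299 without replicate 3 on HP and 2679 without replicate 3 on LP.

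Whether restriction acts differently in the new mutation than in wild type was asked by the interaction of diet with pd1245 against EK. A negative value, called a lower response here and below, means that the log2 change from HP to LP lay further down in pd1245. A lower response is thus not a weaker one, and it can be a larger fall. amn (−1.44, SE 0.30), MTTP, which loads lipid onto apolipoprotein B (−1.09, SE 0.21), and VIL1, the microvillus protein villin (−0.95, SE 0.18), had lower responses to LP in pd1245. So did MELTF, melanotransferrin (−3.71, SE 0.64), gstt1b (−1.13, SE 0.20) and PDIA4 (−1.31, SE 0.25). ODC1, the first enzyme of polyamine synthesis (3.13, SE 0.56), TRIB3 (1.35, SE 0.28) and lepb, a leptin (7.60, SE 1.42), had higher responses. The lepb value had the widest SE of the genes named here, so its size is loosely measured. In EK of experiment 2 lepb was low, at 3.08 ± 1.09 CPM on HP (n = 3) and 0.658 ± 0.511 CPM on LP (n = 4). Of 55 glutathione and antioxidant genes 15 had a lower response and 1 a higher one (21 and 1 adjusted over the list alone; camera adjusted p = 3.57e-11, adjusted p = 0.471 with an estimated correlation). Of 29 anterior enterocyte genes 7 had a lower response (10 adjusted over the list alone; camera adjusted p = 6.77e-07, adjusted p = 0.471 with an estimated correlation). Among cell cycle genes 5 of 78 had a lower response, 19 adjusted over the list alone, and 3 without replicate 3 of pd1245 on LP (camera adjusted p = 1.68e-12, adjusted p = 0.471 with an estimated correlation). In all 1296 genes differed in their response, 523 higher and 773 lower; fitting only these 4 groups gave 361 and DESeq2 gave 2178. The count was 711 and 541 without replicates 1 and 2 of EK on HP, 392 and 503 without replicates 2 and 3 of EK on LP, 401 without replicate 3 of pd1245 on HP and 2907 without replicate 1 of pd1245 on LP.

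Whether the new mutation differs from wild type without restriction was asked on HP. Myelin, fast muscle and matrix genes were lower in pd1245 and keratin genes higher. mbpa, a myelin basic protein, fell from 154 ± 21.2 to 98.5 ± 6.67 CPM and plp1b, a myelin proteolipid, from 55.6 ± 6.70 to 30.9 ± 0.827 CPM (SD, n = 3). myhz2, a fast muscle myosin, fell from 4650 ± 666 to 2200 ± 205 CPM, and bglapl, an osteocalcin relative, from 15.0 ± 2.82 to 2.3 ± 0.814 CPM. ptprq rose from 3.77 ± 0.279 to 35.3 ± 1.66 CPM, krt4, an epidermal keratin, from 4180 ± 121 to 6450 ± 387 CPM and lgals1l1, a galectin, from 10.3 ± 0.392 to 71.3 ± 23.6 CPM. Of 11 myelin genes 4 fell, 10 adjusted over the list alone, and this list kept its call with an estimated correlation (camera adjusted p = 5.94e-13, adjusted p = 0.0195 with an estimated correlation). Fast muscle genes fell in 10 of 33 cases, 16 adjusted over the list alone (camera adjusted p = 1.18e-12, adjusted p = 0.284 with an estimated correlation). Collagen and matrix genes fell in 15 of 59 cases, 32 adjusted over the list alone, among them the collagen-crosslinking oxidase LOX (−0.97) and the prolyl hydroxylase P4HA1 (−0.99) (camera adjusted p = 1.64e-16, adjusted p = 0.469 with an estimated correlation). Of 23 keratinocyte genes 6 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 3.91e-04, adjusted p = 0.469 with an estimated correlation). In all 947 genes changed, 370 higher and 577 lower, and a fit without replicate 3 of pd1245 on LP called 2160. The count was 391 without replicate 2 of EK on HP, and 535 and 395 without replicates 1 and 2 of pd1245 on HP. The same direction was called on both diets for 170 genes higher in pd1245 (59 expected from the numbers called) and 365 lower (91.2 expected), and 26 had opposite directions.

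**Figure D3:**
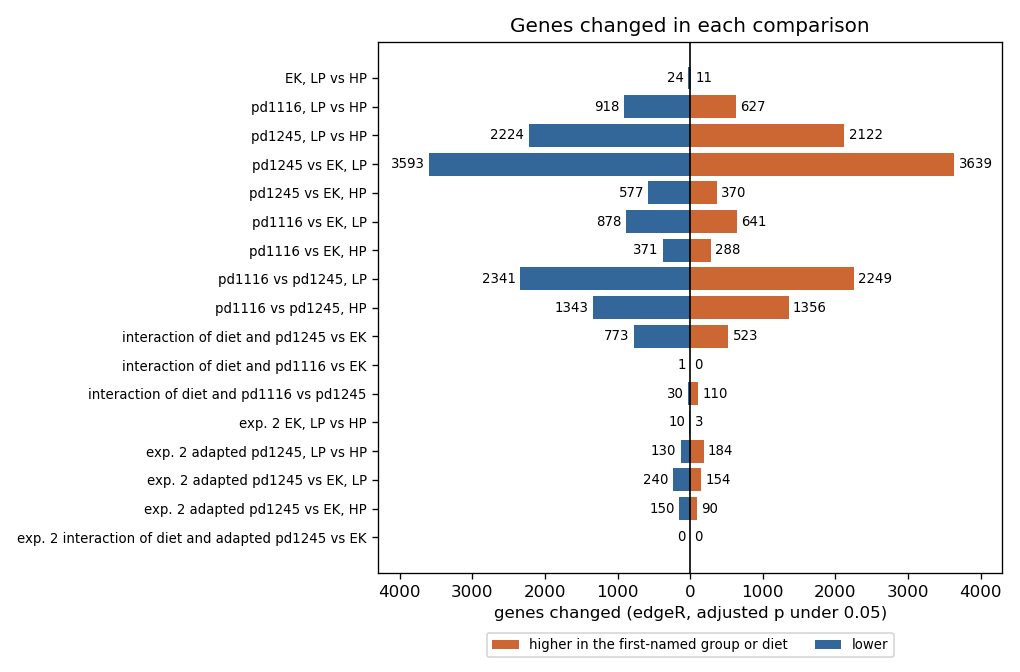
Numbers of genes with adjusted p under 0.05 in each comparison, higher and lower in the first-named group, on the x axis. The bars run from 1 gene for the interaction of diet with pd1116 against EK to 7232 genes for pd1245 against EK on LP, and experiment 2 has no called interaction.

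How wild-type larvae respond to restriction was asked within EK of experiment 1. A few lens, fast muscle and myelin genes were lower on LP, in a small set of changes. myha, a muscle myosin heavy chain, fell from 28.8 ± 13.1 to 6.16 ± 1.59 CPM, and crygm2e, a lens crystallin, from 47.4 ± 6.17 to 21.7 ± 2.96 CPM (SD, n = 3). TTR rose from 1.94 ± 1.07 to 7.85 ± 1.39 CPM, SCARB1, a receptor for high-density lipoprotein, from 47.9 ± 10.1 to 85.2 ± 8.55 CPM and FTCD, an enzyme of histidine breakdown, from 30.4 ± 3.79 to 46.5 ± 2.24 CPM. Of 57 lens crystallin genes 5 fell, 12 adjusted over the list alone (camera adjusted p = 3.06e-18, adjusted p = 0.494 with an estimated correlation). Of 11 myelin genes 2 fell, among them plp1b (−0.69), with 4 adjusted over the list alone (camera adjusted p = 5.7e-09, adjusted p = 0.0881 with an estimated correlation). Of 33 fast muscle genes 2 fell, 4 adjusted over the list alone (camera adjusted p = 3.02e-11, adjusted p = 0.494 with an estimated correlation). In all 35 genes changed, 11 higher and 24 lower. The count was 57 without a filter, 19 with a replicate block, 87 with only these groups, 128 with DESeq2 and 174 without replicate 3 of pd1245 on LP; leaving out 1 EK library gave 2, 3 and 76 without replicates 1, 2 and 3 on HP and 1 without either of replicates 2 and 3 on LP.

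How the old mutation responds to restriction was asked within pd1116. Myelin genes, liver secreted proteins and the lysosomal enzymes of protein-absorbing enterocytes were lower on LP, and a bile acid enzyme was higher. mbpa fell from 216 ± 15.7 to 99.8 ± 14.5 CPM and plp1b from 72.1 ± 2.47 to 33.6 ± 1.75 CPM (SD, n = 3). LGMN fell from 682 ± 42.7 to 291 ± 63.2 CPM and ahsg2 from 222 ± 6.34 to 49.8 ± 22.3 CPM. CYP7A1, the rate-limiting enzyme of bile acid synthesis, rose from 13 ± 6.19 to 56.5 ± 5.78 CPM, and PPARA, a receptor that drives fatty acid oxidation, rose (1.03). cbln6, a cerebellin, fell (log2 fold change −6.62), as did hpxa, a hemopexin (−4.94). Of 11 myelin genes 7 fell (8 adjusted over the list alone), and the call held with an estimated correlation (camera adjusted p = 2.15e-13, adjusted p = 0.0158 with an estimated correlation). Of 27 hepatocyte genes 17 fell and 1 rose (21 and 1 adjusted over the list alone; camera adjusted p = 5.25e-14, adjusted p = 0.229 with an estimated correlation). Of 23 protein uptake genes 9 fell (13 adjusted over the list alone; camera adjusted p = 5.63e-10, adjusted p = 0.229 with an estimated correlation). Of 50 endoplasmic reticulum folding genes 8 fell, with the chaperone HSP90B1 at −0.78 and PDIA4 at −1.15 (16 fell and 1 rose adjusted over the list alone; camera adjusted p = 4.27e-06, adjusted p = 0.442 with an estimated correlation). In all 1545 genes changed, 627 higher and 918 lower; fitting only these 2 groups gave 3603 and a fit without replicate 3 of pd1245 on LP gave 3531. The count was 772, 811 and 519 without replicates 1, 2 and 3 on HP, and 745, 911 and 624 without replicates 1, 2 and 3 on LP. pd1116 and pd1245 shared 256 genes higher on LP (58.5 expected) and 414 lower (89.8 expected), with 27 opposite, while EK and pd1245 shared 2 higher (1.03 expected) and 6 lower (2.35 expected), with 3 opposite. EK and pd1116 shared 5 higher (0.303 expected) and 16 lower (0.969 expected), with 0 opposite.

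How the old mutation differs from wild type was asked on each diet. EMILIN2, an elastin microfibril protein, was high in pd1116 on both diets, at 20.5 ± 1.16 CPM on LP against 0.844 ± 0.133 CPM in EK, and 20.3 ± 1.2 against 1.11 ± 0.105 CPM on HP (SD, n = 3). serpina1, the antitrypsin of liver, rose on LP from 128 ± 13.1 to 273 ± 42 CPM and on HP from 106 ± 5.63 to 366 ± 16.6 CPM. DIO1, which activates thyroid hormone, fell on LP from 41.7 ± 1.92 to 16.1 ± 4.05 CPM and on HP from 36.3 ± 3.63 to 18.5 ± 1.88 CPM. IDI1, an isomerase of cholesterol synthesis, fell on both diets (−0.90 on LP and −0.97 on HP). SLC2A2, the glucose transporter of liver and gut, fell on LP from 62.7 ± 3.97 to 28.3 ± 2.83 CPM, and SLC15A2 rose on HP from 15.2 ± 4.87 to 36.0 ± 4.03 CPM. On LP, 12 of 29 anterior enterocyte genes fell (15 adjusted over the list alone; camera adjusted p = 3.19e-12, adjusted p = 0.439 with an estimated correlation). Of 27 hepatocyte genes on LP 12 fell and 2 rose (20 and 2 adjusted over the list alone; camera adjusted p = 3.19e-12, adjusted p = 0.593 with an estimated correlation). Of the 23 protein uptake genes 9 fell on LP, including ctsbb (−0.98) and LGMN (−0.83) (11 fell and 1 rose adjusted over the list alone; camera adjusted p = 3e-06, adjusted p = 0.884 with an estimated correlation). On HP, 5 of 29 anterior enterocyte genes fell (5 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00205, adjusted p = 0.895 with an estimated correlation), and 2 of 33 photoreceptor genes rose (6 adjusted over the list alone; camera adjusted p = 1.77e-05, adjusted p = 0.895 with an estimated correlation). On LP 1519 genes changed, 641 higher and 878 lower, and on HP 659 changed, 288 higher and 371 lower. The diets shared 169 genes higher (8.12 expected) and 219 lower (14.3 expected), with 1 opposite. On LP the count was 3220 with only the groups compared and 2949 in a fit without replicate 3 of pd1245 on LP; it was 950, 809 and 825 without replicates 1, 2 and 3 of EK, and 980 and 756 without replicates 1 and 3 of pd1116. On HP it was 1029 with only the groups compared and 1245 without replicate 3 of pd1245 on LP; it was 409 without replicate 2 of EK, and 391, 405 and 431 without replicates 1, 2 and 3 of pd1116.

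Whether restriction acts differently in the old mutation than in wild type was asked by the interaction of diet with pd1116 against EK. cbln6 had a lower response in pd1116 (−5.43, SE 0.80, adjusted p = 0.0416) and was the 1 gene called, of 2600 at an unadjusted p under 0.05. PDIA4 (−1.22, SE 0.24, adjusted p = 0.123), amn (−1.11, SE 0.29, adjusted p = 0.185) and lepb (6.34, SE 1.47, adjusted p = 0.147) did not pass. Their values went the same way as in pd1245, so those responses are not shown to be particular to pd1245. The response of VIL1 did differ between the mutations. Of 27 hepatocyte genes 0 passed over all genes and 20 had a lower response adjusted over the list alone (camera adjusted p = 1.6e-22, adjusted p = 0.215 with an estimated correlation). Of 23 protein uptake genes 0 passed over all genes, while 8 had a lower and 1 a higher response adjusted over the list alone (camera adjusted p = 5.84e-07, adjusted p = 0.457 with an estimated correlation). Fitting only these groups called 611 genes, DESeq2 154 and a fit without replicate 3 of pd1245 on LP 254, whereas a strict filter, a replicate block and thinned counts each called 0. Leaving out 1 library gave 0 to 6 genes.

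How the old and new mutations differ under restriction was asked by comparing pd1116 with pd1245 on LP. Genes of cell division, matrix, interferon response and sterol synthesis were higher in pd1116, and ribosomal protein genes lower. tfa stood at 1830 ± 250 CPM in pd1116 against 557 ± 206 in pd1245, CENPF at 32.7 ± 1.3 against 11.0 ± 5.14 CPM, and SLC15A2 at 20.3 ± 3.00 against 3.07 ± 0.820 CPM (SD, n = 3). ctsbb (1.1) and LUM (1.26) were also higher in pd1116, and itln3, an intelectin, was lower (−4.62). Of 78 cell cycle genes 41 were higher (50 adjusted over the list alone), and of 59 matrix genes 31 were higher (36 adjusted over the list alone) (camera adjusted p = 1.67e-17 and 6.84e-16, adjusted p = 0.542 and 0.542 with an estimated correlation). Of 55 interferon response genes 29 were higher and 2 lower (35 and 2 adjusted over the list alone), with the helicase gene helz2b at 1.33 (camera adjusted p = 2.18e-08, adjusted p = 0.542 with an estimated correlation). Of 29 cholesterol synthesis genes 16 were higher (17 adjusted over the list alone; camera adjusted p = 4.23e-07, adjusted p = 0.542 with an estimated correlation). Of 84 ribosomal protein genes 62 were lower and 1 higher (80 and 1 adjusted over the list alone; camera adjusted p = 1.39e-14, adjusted p = 0.744 with an estimated correlation). Without replicate 3 of pd1245 on LP, 7 ribosomal protein genes were lower, and 33 cell cycle, 27 matrix, 22 interferon and 16 cholesterol synthesis genes were higher. In all 4590 genes differed, 2249 higher and 2341 lower in pd1116; fitting only these groups gave 613, and 2324 when replicate 3 of pd1245 was also left out. The count was 2289 without replicate 2 of pd1116 and 2973 without replicate 3 of pd1245.

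The same contrast on HP asked how the mutations differ without restriction. Myelin, digestive enzyme, neuron and red cell genes were higher in pd1116. amy2al2, a pancreatic amylase, stood at 1300 ± 112 CPM against 637 ± 63.9 CPM in pd1245 (SD, n = 3). mbpa (1.13), the neurofilament gene nefma (0.58) and hpxa (6.06) were higher, and lgals1l1 was lower (−5.19). Of 11 myelin genes 9 were higher, 10 adjusted over the list alone, a call that held with an estimated correlation (camera adjusted p = 1.97e-13, adjusted p = 0.0154 with an estimated correlation). Of 30 exocrine pancreas genes 8 were higher (16 higher and 2 lower adjusted over the list alone; camera adjusted p = 7.59e-07, adjusted p = 0.816 with an estimated correlation). Of 27 neuron genes 9 were higher (11 adjusted over the list alone; camera adjusted p = 1.17e-04, adjusted p = 0.68 with an estimated correlation). Of 15 erythrocyte genes 8 were higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 6.45e-07, adjusted p = 0.68 with an estimated correlation). In all 2699 genes differed, 1356 higher and 1343 lower in pd1116, and a fit without replicate 3 of pd1245 on LP called 4563. The count was 1753, 1757 and 1545 without replicates 1, 2 and 3 of pd1116, and 1590 without replicate 2 of pd1245. The diets shared 720 genes higher (134 expected) and 585 lower (138 expected), with 23 opposite.

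Whether the mutations respond differently to restriction was asked by the interaction of diet with pd1116 against pd1245. A positive value means a higher response in pd1116, in the same signed sense, and not a stronger one. fut9d, a fucosyltransferase (2.03, SE 0.27), SLC7A7, which exports cationic amino acids from enterocytes (1.00, SE 0.15), and VIL1 (0.93, SE 0.18) had higher responses. chia.3, a chitinase (−1.96, SE 0.28), and plp1b (−0.87, SE 0.16) had lower responses. Of 57 lens crystallin genes 5 had a lower response, 7 adjusted over the list alone (camera adjusted p = 2.04e-04, adjusted p = 0.658 with an estimated correlation). Of 34 amino acid and peptide transport genes 2 had a higher response (3 adjusted over the list alone; camera adjusted p = 0.0246, adjusted p = 0.59 with an estimated correlation). In all 140 genes differed, 110 higher and 30 lower; a replicate block gave 75, only the groups compared 18, DESeq2 491 and thinned counts 91. Without replicates 1, 2 and 3 the count was 20, 51 and 29 for pd1116 on HP and 28, 51 and 48 for pd1116 on LP, and it was 61 and 24 without replicates 1 and 3 of pd1245 on HP and 496 without replicate 1 of pd1245 on LP.

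**Figure D4:**
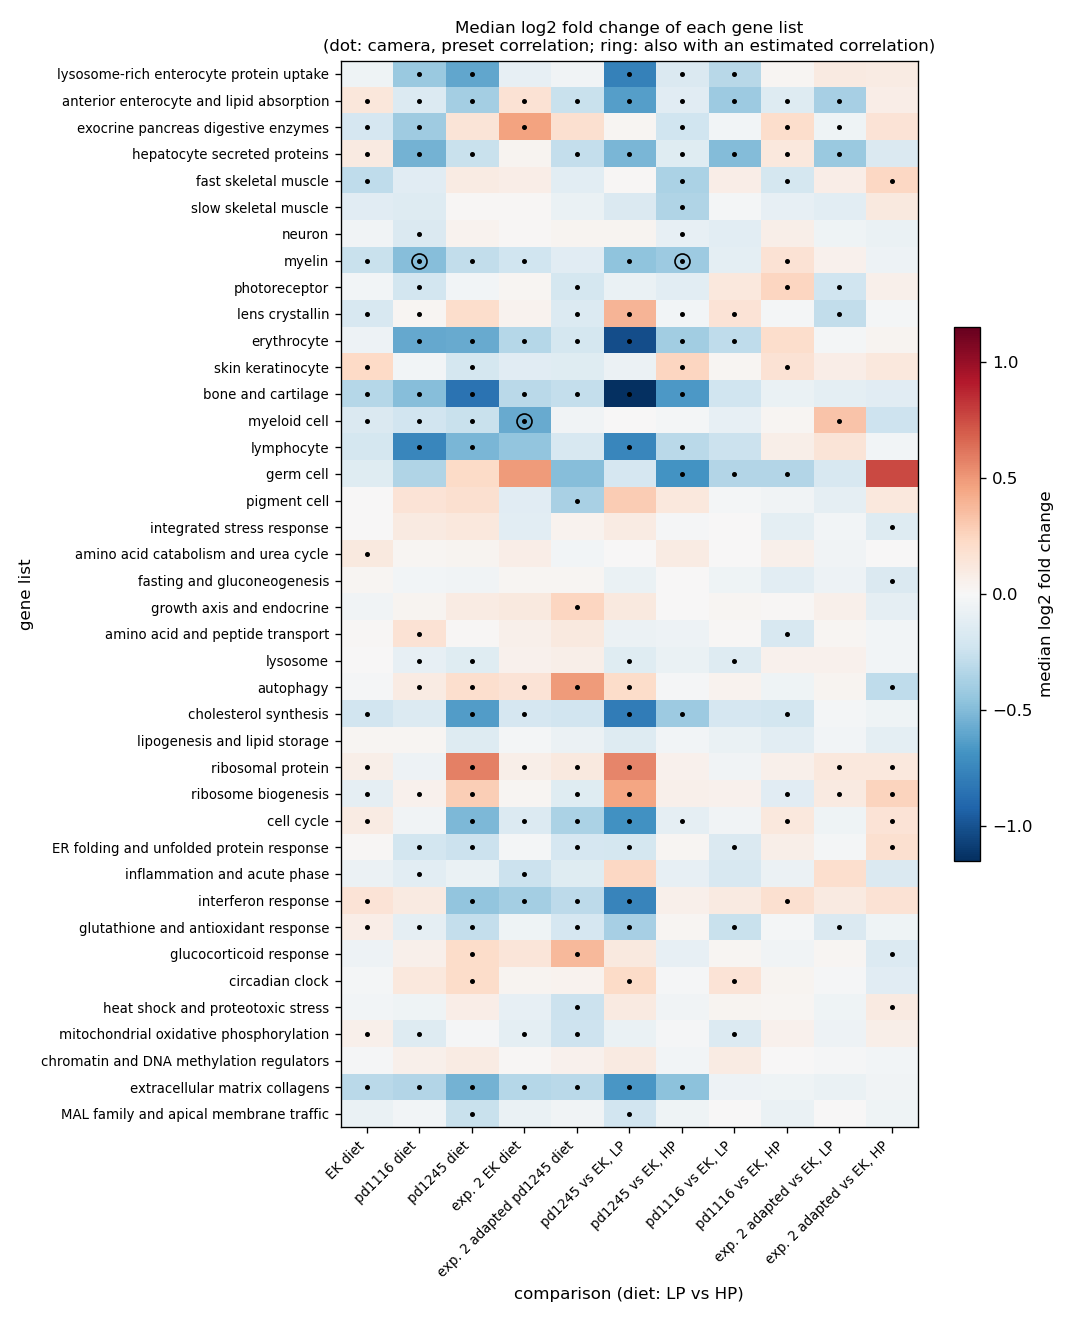
Median log2 fold change of the measured members of each gene list (rows) for diet in each line and for each mutant line against EK (columns), as colour; a dot marks camera adjusted p under 0.05 and a ring a call that also held with an estimated correlation. Myelin carries a ring for the pd1116 diet response and for pd1245 against EK on HP, and myeloid cell for the EK diet response of experiment 2.

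Whether both mutations differ from wild type in the same genes under restriction was asked by overlap. Among genes lower than EK on LP, 520 were called in both mutants (139 expected), including ctsbb and LGMN, and 329 were higher in both (103 expected), with 47 opposite. Both comparisons used the same EK libraries, and across 22742 genes, which are not independent replicates, the fold changes correlated at r = 0.36, below the r of 0.497 (0.471 to 0.521) for simulated groups without any change. Their covariance was 0.11 against 0.030 (0.028 to 0.032) in those simulations. In the simulations 0 genes were called in both, but this was set by their design, which changed no gene. They cannot tell how many shared calls the same EK libraries give where both lines differ. Nor do they cover a deviation common to those EK libraries.

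Experiment 2 asked again how wild-type larvae respond to restriction. Myeloid genes were lower on LP in EK. MMP9, a secreted matrix protease of neutrophils and macrophages, fell from 51.9 ± 9.81 (n = 3) to 17.5 ± 2.37 CPM (n = 4), and npsn, a neutrophil protease, from 35.2 ± 7.09 to 20.1 ± 2.16 CPM. DDX21, a nucleolar RNA helicase, rose from 65.3 ± 9.62 to 147 ± 24.0 CPM. Of 29 myeloid genes 2 fell, 13 adjusted over the list alone, a call that held with an estimated correlation (camera adjusted p = 2.02e-15, adjusted p = 0.0489 with an estimated correlation). Of 30 exocrine pancreas genes 0 passed over all genes and 14 rose adjusted over the list alone (camera adjusted p = 4.14e-11, adjusted p = 0.581 with an estimated correlation). In all 13 genes changed, 3 higher and 10 lower, of 1910 at an unadjusted p under 0.05; the count was 93 without a filter, 28 with a replicate block and 149 with DESeq2. Across 16427 genes, which are not independent replicates, the EK diet responses of the experiments correlated at r = 0.16.

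How the adapted line responds to restriction was asked within adapted pd1245. The autophagy list, which includes FBXO32 and trim63a, was higher on LP, and the cell cycle list was lower. FBXO32, the ubiquitin ligase atrogin-1 of wasting muscle, rose from 2.29 ± 1.25 (n = 3) to 21.7 ± 6.28 CPM (n = 4), and trim63a, the related ligase MuRF1, from 24.2 ± 7.98 to 101 ± 30.4 CPM. ULK2 rose from 29.8 ± 1.27 to 62.2 ± 7.09 CPM, SESN1, a sestrin that restrains mTORC1, from 86.5 ± 15.0 to 237 ± 70 CPM and LPIN1 from 42.8 ± 12.5 to 190 ± 37.6 CPM. MCM6 (ENSDARG00000057683), a subunit of the replicative helicase, fell from 67.9 ± 9.43 to 39.2 ± 3.95 CPM. Of 41 autophagy genes 9 rose, 16 adjusted over the list alone (camera adjusted p = 8.38e-14, adjusted p = 0.369 with an estimated correlation). Of 79 cell cycle genes 4 fell, 21 adjusted over the list alone (camera adjusted p = 7.42e-16, adjusted p = 0.369 with an estimated correlation). Of 40 heat shock genes 5 fell, with the mitochondrial chaperonin HSPD1 at −0.79 (10 adjusted over the list alone; camera adjusted p = 5.15e-05, adjusted p = 0.369 with an estimated correlation). In all 314 genes changed, 184 higher and 130 lower; the count was 550 without a filter, 681 with only these groups, 745 with DESeq2 and 776 without replicate 2 of EK on HP. It was 57 and 78 without replicates 1 and 3 on HP, and 648, 96, 125 and 122 without replicates 1, 2, 3 and 4 on LP. The adapted and the unadapted pd1245 lines shared 104 genes higher on LP (19.7 expected) and 40 lower (15.5 expected), with 4 opposite. The overlap was not particular to pd1245. With pd1116 the adapted line shared 40 genes higher (4.95 expected) and 34 lower (6.72 expected), with 0 opposite. With EK of experiment 2 it shared 3 higher (0.0331 expected) and 4 lower (0.0780 expected), with 0 opposite.

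How the adapted line differs from wild type was asked on each diet. cela1.3, an elastase of the pancreas, stood at 2.98 ± 0.883 CPM in the adapted line against 61.5 ± 18.7 CPM in EK on LP (n = 4) and 4.31 ± 1.25 against 35.9 ± 6.18 CPM on HP (n = 3). CTCF, which organizes chromatin loops, rose on LP from 12.3 ± 2.98 to 29.4 ± 2.08 CPM and on HP from 12.7 ± 2.01 to 33.9 ± 3.44 CPM. znf1156, a zinc finger gene, held 0 counts in every adapted library, which makes it at least 81.8-fold lower than the 5.31 CPM of EK on LP and at least 47.1-fold lower than the 4.26 CPM of EK on HP. IMPACT, an inhibitor of the kinase GCN2, fell (log2 fold change −6.62 on LP and −5.68 on HP), and srsf3a, a splicing factor, rose (1.69 and 1.83). DIO1 fell on LP from 22.4 ± 11.7 to 8.23 ± 0.509 CPM, gpx1a, a glutathione peroxidase, fell on LP (log2 fold change −2.26), and FBXO32 fell on HP from 9.60 ± 0.840 to 2.29 ± 1.25 CPM. On LP 2 of 29 anterior enterocyte genes fell (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 5.69e-07, adjusted p = 0.565 with an estimated correlation). Of 27 hepatocyte genes 2 fell on LP, including the apolipoprotein apom (−0.77) (5 adjusted over the list alone; camera adjusted p = 1.7e-10, adjusted p = 0.795 with an estimated correlation). On HP 1 of 41 autophagy genes fell, 6 adjusted over the list alone (camera adjusted p = 1.62e-04, adjusted p = 0.965 with an estimated correlation). On LP 394 genes changed, 154 higher and 240 lower, 163 with a strict filter and 250 without replicate 2 of the adapted line. On HP 240 changed, 90 higher and 150 lower; the count was 377 without a filter, 115 with a strict filter, 158 with only these groups, and 155, 121 and 152 without replicates 1, 2 and 3 of the adapted line. The diets shared 53 genes higher (0.831 expected) and 96 lower (2.16 expected), with 0 opposite.

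Whether restriction acts differently in the adapted line than in wild type was asked by the interaction within experiment 2. edgeR called 0 genes, of 894 at an unadjusted p under 0.05, and DESeq2 called 1. Of 29 anterior enterocyte genes 0 passed over all genes and 5 had a lower response in the adapted line adjusted over the list alone (camera adjusted p = 2.9e-09, adjusted p = 0.19 with an estimated correlation). Of 29 myeloid genes 1 had a higher response adjusted over the list alone (camera adjusted p = 1.54e-09, adjusted p = 0.19 with an estimated correlation).

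Whether the adapted line differs from EK in the same genes as unadapted pd1245 or pd1116 was asked across the experiments. Only genes tested in both experiments were used. The submitters describe the defect of pd1116 as adapted too. On LP the adapted and unadapted pd1245 lines shared 73 genes lower than EK (42 expected) and 24 higher (25.4 expected), with 51 opposite, and the fold changes correlated at r = 0.15 across genes, which are not independent replicates. The adapted line and pd1116 shared 27 genes lower (10.3 expected) and 12 higher (3.88 expected). Opposite directions were called for 39 genes, more than were shared in either direction, so this overlap shows no agreement in direction. The fold changes correlated at r = 0.02 across genes. This r was −0.06 among genes called in either comparison and −0.02 without replicate 2 of the adapted line on LP. DIO1 was lower than EK in pd1116 and in the adapted line on both diets. IMPACT went opposite ways on HP, lower than EK in the adapted line (−5.68) and higher in pd1116 (2.15, adjusted p = 0.0364).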

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

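Chosen only after the results were seen were the tests of reads outside genes, of oxidative phosphorylation genes, of depth, of effect sizes and of adaptation, and the settings with thinned counts or without a library that stood apart; the spread was also added to the test on neighbours of pllp and on chromosome segments after their values were seen.

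Diet responses that differed between lines by the interaction test are listed here by value. Between pd1245 and EK 1296 genes differed, among them pllp (−1.11), PPP1R27 (3.46), HMOX1, a heme oxygenase (3.28), FRRS1 (ENSDARG00000076183, −4.94), lgals3bp.3 (−4.13) and MELTF (−3.71). HMOX1 in EK held 23.5 ± 23.5 CPM on HP and 5.61 ± 1.11 CPM on LP (SD, n = 3), with overlapping libraries. That EK difference was not called (−2.06, adjusted p = 0.216), yet it makes up part of the 3.28. Of 60 drawn regroupings, which exchanged diet labels within each line, 1, the real one, gave as many as 1296 genes. The highest other gave 947, with only replicate 3 of EK on HP and replicate 1 of EK on LP exchanged. Since it left the pd1245 labels intact, it kept the diet effect of that line. Regroupings of this kind are no measure of equal diet responses, so they cannot exclude chance. Between pd1116 and EK 1 gene differed, cbln6 (−5.43), and 4 of 60 regroupings gave as many. The highest gave 394, with labels of EK alone exchanged and those of pd1116 intact, and chance is not excluded. Between pd1116 and pd1245 140 genes differed, among them FRRS1 (ENSDARG00000076183, 4.82), irg1l (2.96), col8a1a (2.74), crygm2f (−2.35), COCH (−2.20) and crygm7 (−2.08). Here 2 of 60 regroupings gave as many genes. The highest other, with 210, exchanged labels of pd1245 alone and left those of pd1116 intact, so chance is not excluded either. In the adapted line against EK 0 genes differed by edgeR (894 at an unadjusted p under 0.05, 1 by DESeq2), 60 of 60 regroupings gave as many, and the highest other gave 56. In data outside the comparisons, spike-in features held 546 counts over all libraries of experiment 2, and the median share of reads outside genes in experiment 1 was 13.01%.

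For comparisons of 3 libraries with 3, 10 splits are too few to exclude chance; in each, 1 split, the real one, gave as many genes. The real count and the highest other were 35 and 0 for diet in EK, 1545 and 0 in pd1116 and 4346 and 7 in pd1245. They were 7232 and 0 for pd1245 against EK on LP, 947 and 0 on HP, 1519 and 0 for pd1116 against EK on LP and 659 and 1 on HP. They were 4590 and 1 for pd1116 against pd1245 on LP, 2699 and 0 on HP, and 240 and 0 for the adapted line against EK on HP. In experiment 2, 1 of 35 splits, the real one, gave as many genes for diet in EK (13, highest other 3) and diet in the adapted line (314, highest other 156). The same held for the adapted line against EK on LP (394, highest other 16). This share is under 0.05 in each, without adjustment over the comparisons. It argues against a chance split of independent libraries, but differences between tanks or clutches could not be tested.

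Replicate 3 of pd1245 on LP stood apart from the other libraries of its group. Its median over ribosomal protein genes was 1.19 log2 units above HP against 0.16 and 0.13 in replicates 1 and 2, and over bone and cartilage genes −1.59 against −0.43 and −0.54, while over protein uptake genes it was −0.58 against −0.74 and −0.69; over exocrine pancreas genes it was 0.58 against −0.20 and −0.04 and over fast muscle genes 0.31 against −0.14 and −0.07. Reads outside genes made up 13.53% of it, within the 11.92 to 14.27% of experiment 1, which argues against more intronic or intergenic reads; without ribosomal protein genes and its 10 most abundant genes its deviation was 2.13 times that expected, above the 1.25 of the highest of 15 other libraries, which argues against a few abundant genes alone. A stronger form of the same diet response may be a source in part: across genes its difference from replicate 2 correlated with the diet effect of replicate 1 at r = 0.15 (0.26 with replicates 1 and 2 exchanged), but the difference of replicate 2 from replicate 1 correlated with the diet effect of replicate 3 at 0.14, so this is not specific to replicate 3. That form does not account for the 104 oxidative phosphorylation genes, whose median was 0.29 above HP in replicate 3 against −0.19 in replicates 1 and 2 (HP libraries −0.10 to 0.13), and differences in larval size, age or sampling within the group were not tested.

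Some genes differed from EK in the same direction on both diets: 535 in pd1245, 388 in pd1116 and 149 in the adapted line. Variants linked to pllp could cause such changes; among its 100 nearest genes on each side the ratio of such genes to the number expected was 1.46 in pd1245 (6 against 4.12, upper bound 3.17), 2.1 in pd1116 (5 against 2.38) and 1.16 in the adapted line (1, ctcf, against 0.866), which leaves this open. Segments of another parental background could place such genes side by side; the number with another within 5 places was 1.11 times that of random sets in pd1245 (82 against 73.7 ± 10.1), 2.46 times in pd1116 (63 against 25.6 ± 6.7, highest random set 51) and 3.61 times in the adapted line (14 against 3.88 ± 2.68, highest random set 14). The same ratio for genes changed by diet was 0.77, 1.5 and 0.77 in these lines. Only 67.8% of the pd1116 genes and 67.1% of those of the adapted line could be placed, against 85.8% for pd1245, so these explanations stay open beside an effect of the pllp mutation itself.

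On LP 394 genes differed between the adapted line and EK in experiment 2, against 7232 between pd1245 and EK in experiment 1. Depth alone is excluded, since experiment 1 thinned to the depth of experiment 2 still gave 5923. The same effect sizes with less power are excluded too: over 5940 genes called in experiment 1 the median fold change in that direction was 0.56 there and 0.07 in experiment 2 (0.04 to 0.09 without each library in turn), with 64.2% of the same sign. Choosing genes by their call inflates the first value, but with genes chosen without 1 library of each group the median in those held-out libraries was 0.36 to 0.76 over 9 choices, against 0.06 to 0.07 in experiment 2. Adaptation of the line is a candidate explanation that stays open at r = 0.15 across genes, since the library kit and the counting differ between the experiments together with the line.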

How the results depend on the processing

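Settings chosen only after the data were seen were thinned counts, leaving out the most abundant feature, fits without a library that stood apart, and the groups compared without replicate 3 of pd1245 on LP; the others were planned, and where no reason is given the cause was not tested. Upper quartile and RLE scaling and leaving out the most abundant feature kept every count of genes changed within 1.5 times; upper quartile scaling moved the share of higher genes in the interaction of pd1245 with EK from 40.4 to 29.5%. All values below are numbers of genes changed unless a fold change, a correlation or lists are named. With no filter they were 57 (35) for diet in EK, 93 (13) for diet in EK of experiment 2, 550 (314) for diet in the adapted line, 377 (240) for the adapted line against EK on HP and 3 (1) for the interaction of pd1116 with EK, the value as reported in parentheses. With a strict filter, which tests fewer genes, they were 115 (240) and 163 (394) for the adapted line against EK on HP and LP and 0 (1) for the interaction of pd1116 with EK. DESeq2 gave 128 (35) and 149 (13) for diet in EK of experiments 1 and 2, 745 (314) for diet in the adapted line, 2178 (1296), 154 (1) and 491 (140) for the interactions of pd1245 with EK, pd1116 with EK and pd1116 with pd1245, and 1 (0) for that of experiment 2. Counts thinned to the depth of experiment 2 gave 0 (1) and 91 (140) for the last pair of experiment 1.

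A replicate block assumes that replicate numbers pair libraries, which they do not; with it diet in EK gave 19 (35), diet in EK of experiment 2 gave 28 (13), and the interactions of pd1116 with EK and with pd1245 gave 0 (1) and 75 (140).

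Fitting only the groups compared, with a spread estimated from fewer libraries, gave 87 (35), 3603 (1545) and 0 (4346; 4731 at an unadjusted p under 0.05 in edgeR, 4937 with DESeq2 over all groups) for diet in EK, pd1116 and pd1245, and 681 (314) in the adapted line. It gave 3268 (7232) for pd1245 against EK on LP, 3220 (1519) and 1029 (659) for pd1116 against EK on LP and HP, 613 (4590) for pd1116 against pd1245 on LP, 158 (240) for the adapted line against EK on HP, and 361 (1296), 611 (1) and 18 (140) for the interactions of pd1245 with EK, pd1116 with EK and pd1116 with pd1245. Leaving out replicate 3 of pd1245 on LP as well gave 954 for diet in pd1245 and 2324 for pd1116 against pd1245 on LP. A fit of the other groups without that library gave 174 and 3531 for diet in EK and pd1116, 2160 for pd1245 against EK on HP, 2949 and 1245 for pd1116 against EK on LP and HP, 4563 for pd1116 against pd1245 on HP and 254 for the interaction of pd1116 with EK; a fit without replicate 2 of EK on HP of experiment 2 gave 776 for diet in the adapted line.

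Leaving out each library in turn, which leaves fewer samples, gave 1 to 76 for diet in EK, 519 to 911 in pd1116, 1299 to 5890 in pd1245, 11 to 16 in EK of experiment 2 and 57 to 648 in the adapted line. It gave 391 to 770 for pd1245 against EK on HP, 756 to 1036 and 391 to 532 for pd1116 against EK on LP and HP, 2289 to 5933 and 1545 to 2314 for pd1116 against pd1245 on LP and HP, and 250 to 387 and 121 to 274 for the adapted line against EK on LP and HP. Interactions gave 392 to 2907 (pd1245 with EK), 0 to 6 (pd1116 with EK), 20 to 496 (pd1116 with pd1245) and 0 to 1 (experiment 2). Lists called ranged from 9 to 17 for diet in EK of experiment 2, 6 to 16 for the adapted line against EK on HP and 15 to 25 for the interaction of pd1116 with pd1245.

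The fold change of pllp by diet in pd1245 lost its call with only the groups compared (−0.78) and with thinned counts (−0.58), and so did its interaction of pd1245 with EK (−1.12 and −0.87). Its difference between pd1116 and pd1245 on HP gained a call at −0.49 with only the groups compared, −0.48 without replicate 3 of pd1245 on LP and −0.48 with DESeq2, as did the interaction of those lines at 0.84 with DESeq2. Without each library it ranged from −0.84 to −0.77 for pd1116 against EK on HP, 0.12 to 0.55 for pd1116 against pd1245 on LP and 0.60 to 1.04 for their interaction. Uncalled diet effects on pllp changed sign in pd1116 (−0.03 to 0.12), in EK of experiment 2 (−0.21 to 0.01, with 0.00 without replicate 2 on HP) and in the adapted line (−0.05 to 0.17).

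Across genes, the correlation of pd1245 with pd1116 against EK on LP was 0.40 among genes called, 0.49 by rank and 0.32 to 0.40 without each library. That of the adapted line with pd1245 was 0.17, 0.19 and 0.11 to 0.19, and that with pd1116 was −0.06, 0.14 and −0.02 to 0.04; that of diet in EK between experiments was 0.26 among genes called and 0.13 to 0.18.

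With an estimated correlation camera called 1 list each, in place of 21, 17, 15 and 14, for diet in pd1116, pd1245 against EK on HP, pd1116 against pd1245 on HP and diet in EK of experiment 2, and 0 in every other comparison, where the preset called 9 to 24. fry called 1, 8, 21, 1 and 2 for diet in EK, in pd1116, in pd1245, in EK of experiment 2 and in the adapted line, 21 and 5 for pd1245 against EK on LP and HP, 3 and 0 for pd1116 against EK on LP and HP, 10 and 5 for pd1116 against pd1245 on LP and HP, 2 for the interaction of pd1245 with EK, and 0 for the other interactions and both comparisons of the adapted line with EK.

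Of 1341 values for genes other than pllp named by the rule, 1332 kept their call with RLE, 1336 with DESeq2, 1249 with a block and 960 with only the groups compared, and none of these reversed in any setting. In simulated data with 200 changed genes, depth and replication recovered 20.9, 64.2 and 93.9% of genes changed by 0.5, 1 and 2 log2 units for diet in EK, 6.0, 47.8 and 95.5% in experiment 2, and 0.0, 23.9 and 78.8% for the interaction of experiment 2, with 4 to 11 false calls.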

Other observations

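The test of a smaller diet response in the same genes, in both directions, was chosen only after the result was seen; the other values here come from the tests of the gene lists.

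Circadian clock genes were higher in pd1245 than in EK on LP: 16 of 37 rose and 1 fell (camera adjusted p = 1.56e-04, adjusted p = 0.316 with an estimated correlation; 16 and 1 adjusted over the list alone). nfil3-5, a repressor of clock output (1.12), rorcb, an activator (1.00), and BHLHE40, a repressor (0.96), were among them. In pd1116 on LP 4 of 37 rose, with PER3 at 0.48 (camera adjusted p = 0.00706, adjusted p = 0.963 with an estimated correlation; 11 rose and 1 fell adjusted over the list alone). The labels give no time of day of sampling.

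Lymphocyte and interferon response genes were also lower in pd1245 than in EK on LP. RAG1, which recombines antigen receptor genes, went from 9.02 ± 0.264 to 3.06 ± 0.774 CPM (SD, n = 3), and 7 of 15 lymphocyte genes fell (7 adjusted over the list alone; camera adjusted p = 0.00132, adjusted p = 0.3 with an estimated correlation). Interferon response genes fell in 18 of 55 cases and rose in 1, with the guanylate-binding protein gene gbp1 at −1.30 (19 and 1 adjusted over the list alone; camera adjusted p = 3.78e-05, adjusted p = 0.411 with an estimated correlation), and 13 fell without replicate 3 of pd1245 on LP. gch2, which starts pteridine pigment synthesis, fell (−1.24) and SLC45A2, a melanosome transporter, rose (1.2). CSAD, which makes taurine, fell (−1.73), as did PIWIL1, a germ cell PIWI protein (−1.08), and DMGDH, of choline breakdown, rose (1.00).

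The diet responses of pd1116 and pd1245 mostly shared their direction. Of the 4346 genes changed by diet in pd1245, 81.8% went the same way in pd1116 and 48.1% in EK, and of the 1545 genes changed by diet in pd1116, 85.6% went the same way in pd1245 and 76.0% in EK. Choosing genes called in 1 line favours a smaller median in the other: it was 0.21 log2 units in pd1116 against 0.55 in pd1245 for the first set, and 0.34 in pd1245 against 0.59 in pd1116 for the second. Whether the response of pd1116 is the smaller one stays open, and the genes are not independent of each other.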
